A study of Arabidopsis thaliana with 12 samples.

How the data were processed

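RNA from 12 samples of Arabidopsis thaliana seedlings, 2 to 3 weeks old, was measured by poly(A) RNA sequencing with 75 bp reads from a kit that marks the strand. Per the labels, seedlings grew on medium with 1% sucrose at 20 °C under 16 h light and 8 h dark, and libraries were made from 1 µg of RNA with 7 PCR cycles. The 4 groups, with 3 samples each, were wild type Col-0 and the mutant hda9-1, each without abscisic acid (ABA) and after a spray with 50 µM ABA for 4 h. The labels conflict on treatment. Their treatment field gives no ABA for every wild-type sample and ABA for every hda9-1 sample, whereas the sample titles give both treatments in both genotypes. Groups were taken from the titles. The titles call the 3 samples of a group biological replicates, and the labels do not say whether they came from separate cultures, so the p-values measure the spread between these samples.

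The deposited table holds counts per gene, as whole numbers, for 23911 genes in 12 samples. Per the labels, the authors named Bowtie2, Salmon, limma 3.56 and the TAIR10 build, without saying which tool made the table, so the counts may be alignments or rounded estimates. No further normalization was found in the values. Gene identifiers were matched to the TAIR10.1 annotation, which gave a record for 23655 of them. The other 256 include 170 organelle genes, 88 of the chloroplast and 82 of the mitochondrion, which were recognised by their identifiers. Library totals ran from 42703802 to 52820930 counts. Intervals and floors given for single low counts cover counting error only, since the PCR copies carry no molecular identifiers.

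Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 20924 genes holding 99.99% of all counts. Libraries were scaled by TMM, and 1 quasi-likelihood model with robust estimation and 4 group means was fitted to all 12 samples. Its 5 contrasts were the ABA response in wild type, the ABA response in hda9-1, hda9-1 against wild type without ABA and with ABA, and the difference of the ABA responses, which is the interaction of genotype and treatment. Tests were two-sided. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 within a contrast. Fold changes are log2 values from edgeR with their standard error (SE). Levels are TMM-scaled CPM values as mean ± SD with n = 3. Where 1 group held 0 counts in all its libraries, the fold was bounded with a floor of 3 counts over the group, and with 1 to 3 counts in a group it was given as a ratio with its 95% Poisson interval.

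Groupings, comparisons, tests, gene lists, the rule for naming genes and most alternative settings were fixed before the data were examined. The 30 lists were ABA-induced markers, clade A PP2C phosphatases, PYR/PYL ABA receptors, SnRK2 kinases with ABA transcription factors, and ABA synthesis with catabolism. They also held alternative respiration, mitochondrial stress markers, the nuclear-encoded respiratory chain, superoxide dismutases with catalases, the ascorbate-glutathione cycle with glutathione peroxidases, peroxiredoxins with thioredoxins, NADPH oxidases and glutathione S-transferases. Further lists were nuclear-encoded photosynthesis, leaf senescence, histone deacetylases with HDA9 partners, flowering regulators, seed maturation, salicylic acid with pathogen defence, jasmonate, touch with early stress response, heat shock proteins, the circadian clock, auxin response and the mitotic cell cycle. Markers of root tissue, guard cells and floral organs, and the genes of the chloroplast and of the mitochondrion, completed the set. Each list was tested against all other tested genes by camera on limma 3.58.1 voom values with a preset correlation of 0.01, adjusted over the 30 lists within a contrast. Camera with an estimated correlation and fry were alternatives, and medians of lists are medians of edgeR fold changes. A list is given as called or not called by camera with the preset correlation unless another test is named.

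Genes were named by a fixed rule. HDA9 came first. In each comparison the 6 largest increases and 6 largest decreases followed, among called nuclear genes without overlap between the groups and with at least 5 CPM in the higher group. Each list gave the 3 called members with the smallest p in its more common direction and 1 in the other, or its member with the smallest p where none was called. The text gives part of these, and symbols follow the reference annotation.

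The alternative settings fixed then were RLE factors, upper-quartile factors, library size alone, no filter, a filter of 1 CPM in 3 samples, limma-voom, DESeq2 1.42.0, a fit on the 2 groups compared only, the replicate number as a block, organelle genes left out, an adjusted p below 0.01, and each library left out in turn. Removal of each library's trend with exon length and GC content, alone or without hda9-1 with ABA replicate 2, was added after the data were seen. The replicate numbers did not pair the samples. Among 18 pairs of samples with the same number, correlations of deviations from the group means ran from -0.153 to 0.121, and 0 samples matched best with their own number in every other group. Shares of counts in organelle genes, exon length trends and replicate spread were examined for each library.

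The procedure was tested on simulated data drawn from negative binomial distributions with the library sizes of these samples. Means were those of wild type without ABA in all groups, with 1 dispersion per gene, and genes were drawn independently. Of 100 genes changed 2-fold, 62 to 79 were called in the comparisons of 2 groups and 49 for the difference of responses. At 4-fold these numbers were 88 to 93, and 85. Between 5 and 12 unchanged genes were called among at least 20549. A list of 30 genes raised 1.5-fold was found both with the preset and the estimated correlation (adjusted p = 3.2e-67 and 1.2e-06), with 0 of the other lists called among 29 tested. Since the simulated genes were independent, this does not show how the list tests behave where genes move together.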

Results

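Messenger RNA was measured in 12 samples of Arabidopsis seedlings, 3 in each of 4 groups. The groups were wild type and hda9-1, a mutant of the histone deacetylase gene HDA9, each without ABA and 4 h after a spray with 50 µM ABA. ABA is the plant hormone of drought and salt stress. The study's title concerns HDA9 and the redox systems of mitochondria and chloroplasts under ABA signalling. The data columns name the untreated samples 0 h and the treated samples 4 h, and no mock spray is listed, so ABA cannot be told apart from 4 h of elapsed time or from time of day. Totals ran from 42703802 to 52820930 counts per sample, with 21510 to 22189 genes detected. The first principal component held 58.0% of the variance and the second 12.8%. The median SD within a group was 0.105 and 0.104 log2 in wild type without and with ABA, and 0.122 and 0.170 in hda9-1 without and with ABA.

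HDA9 (AT3G44680, chromosome 3, 16226519 to 16230009, minus strand, TAIR10.1, 14 exons) was lower in every hda9-1 sample than in every wild-type sample. Its level was 16.2 ± 0.721 CPM in wild type without ABA and 5.34 ± 0.583 CPM in hda9-1 (SD, n = 3), so 32.9% of the wild-type level remained. With ABA the levels were 16.6 ± 0.252 and 5.16 ± 0.344 CPM, and 31.2% remained. Counts were 708 to 947 per wild-type sample and 228 to 284 per mutant sample. The log2 fold change was -1.60 ± 0.12 without ABA (SE, adjusted p = 1.2e-05) and -1.68 ± 0.12 with ABA (adjusted p = 6.7e-06). The file does not hold HDA10, a partial copy of HDA9, and the other partial copy, HDA17, had 0 to 2 counts per sample. On a scale from untreated (0) to treated (1) wild type, built from genes that changed 2-fold with ABA in wild type, hda9-1 samples titled without ABA lay between -0.0236 and 0.0342. Those titled with ABA lay between 0.998 and 1.04, so expression parted them as the titles do.

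**Figure D1:**
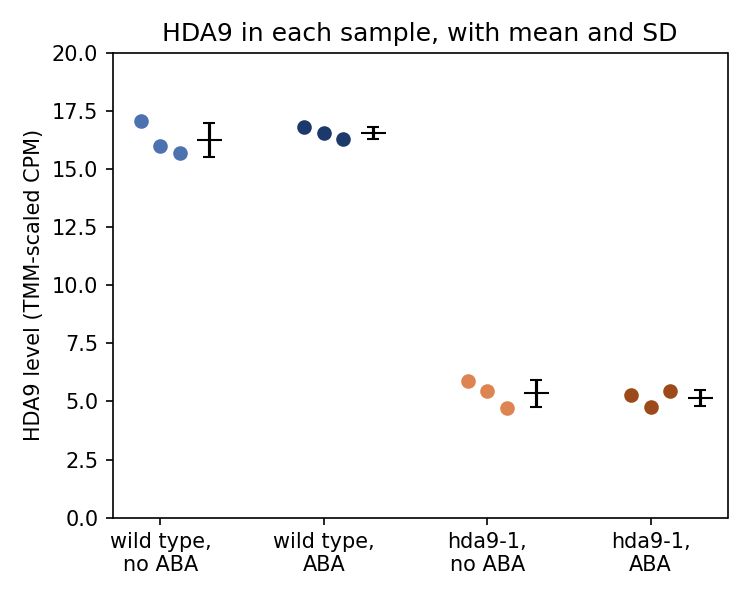
HDA9 level in TMM-scaled CPM (vertical axis) for the 3 samples of each of the 4 groups, as points, with the group mean and SD. The 6 hda9-1 samples lie below the 6 wild-type samples, and the group means are 16.2 and 16.6 CPM in wild type against 5.34 and 5.16 CPM in hda9-1.

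After ABA, LEA7 and LEA4-5, genes of late embryogenesis abundant proteins, which protect cells during drying, were among the largest increases in wild-type seedlings. LEA7 (AT1G52690) went from 0.127 ± 0.151 to 205 ± 31.5 CPM (log2 fold change 10.70 ± 0.62), and LEA4-5 (AT5G06760) rose by 9.62 ± 0.29. The lipid transfer protein gene LTP4 (AT5G59310) rose by 8.08 ± 0.49 and AT5G50360 by 8.29 ± 0.50. AT5G28520 rose 1622-fold (95% counting interval 291 to 64092) and AT5G24080 714-fold (197 to 5903), each from at most 2 counts in untreated wild type. Here and below, largest changes are those among called nuclear genes of at least 5 CPM in the higher group without overlap between the groups. The largest decreases were of AT3G12900, 625-fold (173 to 5164) and down to 2 counts, and of the ABA receptor gene PYL6 (AT2G40330), from 14.1 ± 5.78 to 0.153 ± 0.11 CPM (-6.53 ± 0.63). AT5G59680 (-5.03 ± 0.55), AT1G05700 (-4.72 ± 0.41), AT3G20380 (-4.51 ± 0.20) and AT1G44050 (-4.40 ± 0.45) followed. edgeR called 6474 of 20924 genes, 3551 higher and 2923 lower, of which 1298 and 750 changed at least 2-fold. With upper-quartile factors the split was 3024 higher and 3964 lower, and without WT_ABA replicate 3 the number lower was 1893. Groups did not overlap at 10797 genes (51.6%, against 10% by chance), and 4082 calls (63.1%) held whichever 1 library was left out.

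Genes of ABA signalling changed together in wild type. All 22 ABA-induced markers rose (adjusted p = 7.8e-32 by camera, 0.013 with an estimated correlation), with a median log2 fold change of 4.14. Among them LTI65 (AT5G52300, also RD29B), a dehydration-response gene, rose from 1.02 ± 0.287 to 181 ± 23.3 CPM (7.46 ± 0.19), HB-7 (AT2G46680, also ATHB7) by 4.17 ± 0.11 and AFP1 (AT1G69260) by 4.12 ± 0.13. All 9 clade A PP2C phosphatases, which restrain ABA signalling, rose (adjusted p = 1.1e-14, 0.013 with an estimated correlation), as ABI2 (AT5G57050) by 3.94 ± 0.11, PP2CA (AT3G11410) by 3.51 ± 0.13 and ABI1 (AT4G26080) by 2.90 ± 0.09. Of the SnRK2 kinases and ABA transcription factors 6 of 8 rose (adjusted p = 1.1e-06, 0.016 with an estimated correlation), among them ABF3 (AT4G34000) by 2.40 ± 0.09, ABF2 (AT1G45249) by 2.16 ± 0.11 and the guard cell kinase gene OST1 (AT4G33950) from 17.5 ± 2.01 to 42.9 ± 4.88 CPM. Of the genes of ABA synthesis and catabolism 8 of 12 rose (adjusted p = 1.9e-06, 0.014 with an estimated correlation), on both arms of the pathway. The ABA 8'-hydroxylase genes CYP707A1 (AT4G19230) and CYP707A2 (AT2G29090) rose by 4.57 ± 0.14 and 5.42 ± 0.28, and the synthesis gene ABA1 (AT5G67030) by 1.48 ± 0.13. The PYR/PYL receptors fell at 6 of 10 members and rose at 1 (adjusted p = 0.030, and adjusted p = 0.60 with an estimated correlation), with 2 higher and 6 lower adjusted over the list alone. PYL4 (AT2G38310) fell from 49.7 ± 9.56 to 4.4 ± 0.476 CPM and PYR1 (AT4G17870) fell by 0.91 ± 0.15, while PYL7 (AT4G01026) rose by 0.61 ± 0.15. The receptor list was not called without WT_ABA replicate 2 (adjusted p = 0.059). Numbers adjusted over the list alone equal those given for the other 4 lists.

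Senescence and stress lists rose as well in wild type. Of the leaf senescence genes 12 of 14 rose (adjusted p = 1.3e-07, 0.040 with an estimated correlation; 12 adjusted over the list alone), as SAG29 (AT5G13170) by 3.60 ± 0.19, NAC6 (AT5G39610, also ORE1), a regulator of leaf ageing, by 1.90 ± 0.14 and ACD1 (AT3G44880, also PAO), a chlorophyll breakdown enzyme, by 1.37 ± 0.10. Of the jasmonate genes 8 of 13 rose (adjusted p = 0.0028, and adjusted p = 0.46 with an estimated correlation; 8 adjusted over the list alone), as JAZ1 (AT1G19180) by 1.52 ± 0.15 and AOS (AT5G42650) by 1.09 ± 0.23. Of the heat shock proteins 8 of 14 rose (adjusted p = 0.0034, and adjusted p = 0.35 with an estimated correlation), as HSP70 (AT3G12580) by 1.93 ± 0.11, and 8 were higher and 1 lower adjusted over the list alone. Of the touch and early stress genes 6 of 11 rose (adjusted p = 0.030, and adjusted p = 0.56 with an estimated correlation), as DREB2A (AT5G05410) by 2.48 ± 0.16, and 6 were higher and 1 lower adjusted over the list alone. That list was not called without WT_noABA replicate 1 (adjusted p = 0.056) or hda9_ABA replicate 2 (adjusted p = 0.054). Of the mitotic cell cycle genes 3 of 10 fell (adjusted p = 0.0084, and adjusted p = 0.60 with an estimated correlation; 4 adjusted over the list alone), as the cyclin gene CYCB2;2 (AT4G35620) with -0.85 ± 0.23. Whichever library was left out, 5 of the 8 jasmonate calls and 1 of the 3 mitotic calls held.

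Among redox and organelle lists in wild type, only the NADPH oxidases, which make superoxide at the cell surface, were called by camera (adjusted p = 0.030, and adjusted p = 0.60 with an estimated correlation). Of these 5 of 8 fell and 1 rose, with 2 higher and 5 lower adjusted over the list alone. The log2 fold change was -2.64 ± 0.17 for AT4G25090 (RBOHG), -2.12 ± 0.26 for RBOHB (AT1G09090), -1.15 ± 0.10 for RBOHD (AT5G47910) and 1.55 ± 0.13 for AT1G19230 (RBOHE). The call ended when trends with exon length and GC content were removed (adjusted p = 0.092). Other redox members moved both ways. Alternative respiration had 5 higher and 3 lower of 12, with the alternative oxidase gene AOX1A (AT3G22370) up by 0.86 ± 0.14, the dehydrogenase gene NDB2 (AT4G05020) up by 0.93 ± 0.08 and NDB4 (AT2G20800) at -2.67 ± 0.62. AOX2 (AT5G64210) rose 77.1-fold from 3 counts (26.0 to 377). The ascorbate-glutathione list had 6 higher and 4 lower of 25, with GPX2 (AT2G31570) up by 1.47 ± 0.13, MDHAR (AT3G09940) at -2.45 ± 0.27, and APX2 (AT3G09640) at least 84.5-fold higher. Superoxide dismutases and catalases had 3 higher and 4 lower of 11, with CAT3 (AT1G20620) up by 0.69 ± 0.11 and the plastid iron enzyme gene FSD3 (AT5G23310) at -0.80 ± 0.18. Peroxiredoxins and thioredoxins had 1 higher and 7 lower of 30, with TPX2 (AT1G65970) at -1.91 ± 0.34, the plastid reductase gene NTRC (AT2G41680) at -0.45 ± 0.09 and TRX5 (AT1G45145) up by 1.17 ± 0.22. The adjusted p of these 4 lists was 0.21, 0.32, 0.86 and 0.32. Adjusted over the list alone they had 5 and 3, 6 and 4, 4 and 4, and 1 and 7 members higher and lower.

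The other 15 lists were not called by camera with the preset correlation in wild type. They had, as higher and lower members, 3 and 0 of 9 for mitochondrial stress markers, 4 and 2 of 25 for the respiratory chain, 2 and 1 of 10 for glutathione S-transferases, 3 and 4 of 51 for photosynthesis, and 2 and 5 of 17 for histone deacetylases. Flowering regulators had 3 and 0 of 11, seed maturation 2 and 0 of 5, salicylic acid genes 0 and 3 of 13, the clock 5 and 1 of 13, auxin genes 3 and 1 of 12, root markers 0 and 4 of 18, and guard cell markers 2 and 2 of 8. Floral markers had 0 of 3, chloroplast-encoded genes 0 of 78 and mitochondrially encoded genes 0 of 25 called. Examples were AGL20 (AT2G45660, also SOC1), a flowering activator, up by 1.14 ± 0.13, the clock gene CCA1 (AT2G46830) up by 1.62 ± 0.17, the seed gene GEA6 (AT2G40170) up by 6.63 ± 0.47, and the small Rubisco subunit gene RBCS1B (AT5G38430) down from 85.7 ± 15.3 to 32.4 ± 5.06 CPM. The iron transporter gene IRT1 (AT4G19690) fell by 2.49 ± 0.40 and the root auxin transporter gene EIR1 (AT5G57090) fell by 1.14 ± 0.12. Root markers were called without WT_ABA replicate 3 (adjusted p = 0.044), and chloroplast-encoded genes without WT_noABA replicate 3 (adjusted p = 0.0084) or WT_ABA replicate 1 (adjusted p = 8.8e-04). The median, mean and test differed in sign for the respiratory chain, glutathione S-transferase, salicylic acid, clock, auxin, floral and mitochondrially encoded lists.

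In hda9-1 the genes LEA7 and LEA4-5 were again among the largest increases after ABA. LEA7 rose by 9.96 ± 0.58, LEA4-5 by 9.78 ± 0.30 and the phosphatase gene HAI3 (AT2G29380) by 9.83 ± 0.36, from 0.0287 ± 0.025 to 28.1 ± 2.71 CPM. CSLG2 (AT4G24000) was at least 474-fold and AT5G24080 at least 380-fold higher, and TSPO (AT2G47770) rose 2067-fold (572 to 17075) from 2 counts. The largest decreases were of PYL6 (-6.40 ± 0.69), AT1G05700 (-5.13 ± 0.45), CYP82C4 (AT4G31940, -4.25 ± 0.57), AT3G23510 (-4.17 ± 0.31), AT3G20380 (-4.03 ± 0.20) and AT3G01260 (-3.98 ± 0.30). AT3G12900 lay below the limit of 5 CPM, with 3.99 ± 2.56 CPM in untreated hda9-1 and 0 counts after ABA, and was called lower (adjusted p = 3.9e-05). edgeR called 8767 genes, 4874 higher and 3893 lower, of which 1861 and 731 changed at least 2-fold. With upper-quartile factors the split was 4298 higher and 4855 lower, and after removal of length trends 4125 and 4807. Groups did not overlap at 9762 genes (46.7%), and 6066 calls (69.2%) held whichever 1 library was left out.

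All 22 ABA-induced markers (median 4.27, adjusted p = 2.2e-25, 0.017 with an estimated correlation) and all 9 clade A PP2C phosphatases (adjusted p = 8.6e-12, 0.017 with an estimated correlation) rose in hda9-1, as LTI65 by 8.36 ± 0.22 and ABI1 by 2.86 ± 0.09. Of the ABA synthesis and catabolism genes 9 of 12 rose (adjusted p = 1.7e-05, 0.017 with an estimated correlation), as CYP707A1 by 4.71 ± 0.14. SnRK2 kinases and ABA transcription factors had 6 of 8 higher (adjusted p = 2.6e-04, and adjusted p = 0.061 with an estimated correlation), as ABF2 by 2.61 ± 0.12, and leaf senescence 11 of 14 (adjusted p = 4.3e-06, and adjusted p = 0.071 with an estimated correlation), as ACD1 by 1.63 ± 0.10. Jasmonate (8 of 13, adjusted p = 0.0044, and adjusted p = 0.51 with an estimated correlation), touch (9 of 11, adjusted p = 0.0044, and adjusted p = 0.45 with an estimated correlation) and heat shock genes (9 of 14, adjusted p = 0.0030, and adjusted p = 0.31 with an estimated correlation) rose. Of the mitotic genes 3 of 10 fell (adjusted p = 0.024, and adjusted p = 0.56 with an estimated correlation), a call lost without hda9_noABA replicate 3 (adjusted p = 0.095) or hda9_ABA replicate 2 (adjusted p = 0.15). Adjusted over the list alone, 11 heat shock genes were higher and the other numbers were equal. After removal of length trends 5 touch genes were higher and 6 mitotic genes lower, and 5 of the 9 touch calls and 1 of the 3 mitotic calls held whichever library was left out.

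In hda9-1 21 of 78 chloroplast-encoded genes rose after ABA (adjusted p = 0.0010, and adjusted p = 0.56 with an estimated correlation), 6 adjusted over the list alone. Examples were ATCG00210 by 1.49 ± 0.28 and ATCG00830 by 3.19 ± 0.66, and 5 of the 21 calls held whichever library was left out. The share called higher was near that over all genes, where 4874 of 20924 were higher. Poly(A) libraries hold few organelle reads, here 0.0756 to 0.199% of counts for the chloroplast and 0.00355 to 0.00825% for the mitochondrion. Redox lists were not called by camera with the preset correlation, and their members went both ways. Peroxiredoxins and thioredoxins had 7 higher and 3 lower of 30, with TRX5 up by 2.04 ± 0.22 and NTRC at -0.66 ± 0.09. The ascorbate-glutathione list had 10 higher and 4 lower of 25, with DHAR1 (AT1G19570) up by 1.46 ± 0.13, and the respiratory chain 9 higher and 2 lower of 25, with CYTC-2 (AT4G10040) up by 1.65 ± 0.24. Short genes moved up in this comparison. The median log2 fold change was 0.28 for the shortest genes (exon length up to 1273 nt) and -0.15 for the longest (at least 2368 nt), against -0.04 and -0.03 in wild type, and the median exon length was 1110.5 nt for peroxiredoxins and thioredoxins against 1766 nt for all tested genes. Other lists not called had, as higher and lower members, 1 and 6 for PYR/PYL receptors, 6 and 1 for alternative respiration, 3 and 0 for mitochondrial stress, 4 and 1 for superoxide dismutases, 2 and 4 for NADPH oxidases, 5 and 1 for glutathione S-transferases, and 9 and 9 for photosynthesis. After removal of length trends the numbers higher and lower were 5 and 11 for peroxiredoxins and thioredoxins, 5 and 6 for the respiratory chain, 8 and 5 for the ascorbate-glutathione list, 2 and 1 for superoxide dismutases and 2 and 27 for photosynthesis. Photosynthesis (mean -0.24, adjusted p = 4.8e-04) and receptors (adjusted p = 0.025) were then called. Receptors were also called without hda9_ABA replicate 1 (adjusted p = 0.036), glutathione S-transferases without hda9_ABA replicate 2 (adjusted p = 0.032) and photosynthesis without hda9_noABA replicate 3 (adjusted p = 0.041). The root list's median, 0.09, differed in sign from its mean and test.

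The responses to ABA of both genotypes overlapped. Of the called genes 5176 changed in the same direction in both, 3043 higher and 2133 lower, where independent calls would give 827 and 544. Fold changes correlated across genes at r = 0.84 and rho = 0.75, though genes are not independent replicates. Another 1293 genes were called in wild type alone and 3586 in hda9-1 alone, and 87.7% and 87.4% of these had the same sign in the other genotype. The larger number in hda9-1 depended on the fit. A fit on the 2 groups compared called 8369 genes in wild type and 6929 in hda9-1. Genes without overlap between the groups were also more in wild type (10797) than in hda9-1 (9762). Only 5 genes were called in opposite directions, and they are named although chosen after their values were seen. They were TOM6 (AT1G49410, -0.44 in wild type and 0.43 in hda9-1), AT1G76770 (-3.30 and 2.79), AT3G19660 (-0.66 and 0.56), AT3G61560 (-0.45 and 0.49) and APT4 (AT4G12440, -2.34 and 2.45), and the difference was not called at any of them (adjusted p 0.217 to 0.232).

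**Figure D2:**
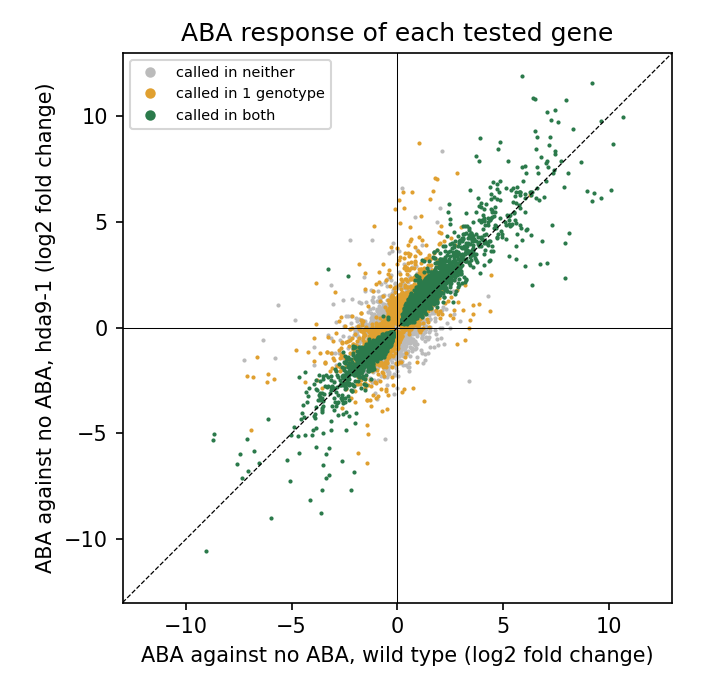
Log2 fold change with ABA of each tested gene in wild type (horizontal axis) and in hda9-1 (vertical axis), coloured by the comparisons in which edgeR called it. Points follow the diagonal (r = 0.84), and 5176 genes were called in both genotypes in the same direction.

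Without ABA, hda9-1 differed from wild type by smaller steps. Among the largest increases were AT5G56370, from 2.09 ± 0.226 to 6.6 ± 1.4 CPM (1.66 ± 0.24), SAG29, from 2.29 ± 0.101 to 5.65 ± 0.554 CPM, and the cytochrome P450 gene CYP81D11 (AT3G28740), from 101 ± 11.1 to 231 ± 29.5 CPM (1.19 ± 0.12). Among the largest decreases were AT4G12490 (-2.54 ± 0.45), AT1G26250, from 49.7 ± 13.6 to 8.88 ± 4.37 CPM (-2.49 ± 0.52), and AT5G26270 (-2.32 ± 0.32). DIN11 (AT3G49620) had the largest decrease, -4.56 ± 1.19, with 7.12 ± 9.41 CPM in wild type, and lost its call without WT_noABA replicate 3 (adjusted p = 0.071), WT_ABA replicates 1, 2 or 3 (0.054, 0.051 and 0.052), hda9_noABA replicates 1, 2 or 3 (0.055, 0.099 and 0.13) or hda9_ABA replicate 1 (0.054). AT2G25510 (-2.64 ± 0.61) and AT5G42530 (-2.62 ± 0.64) lost their calls without WT_noABA replicates 2 (adjusted p = 0.070 and 0.080) or 3 (0.057 and 0.073) or hda9_noABA replicates 2 (0.082 and 0.064) or 3 (0.081 and 0.094), the second gene also without hda9_noABA replicate 1 (0.065). AT1G58848 (1.27 ± 0.38) lost its call without WT_noABA replicates 1, 2 or 3 (adjusted p = 0.096, 0.12 and 0.13), WT_ABA replicate 1 (0.056), hda9_noABA replicate 1 (0.17) or hda9_ABA replicate 3 (0.051). AT3G49160 (1.41 ± 0.31) lost its call without WT_noABA replicate 2 (adjusted p = 0.056) and DOGT1 (AT2G36800, 1.32 ± 0.30) without hda9_noABA replicate 3 (adjusted p = 0.055). PWR (AT3G52250), the gene of a partner protein of HDA9, rose from 124 ± 12.6 to 224 ± 11.4 CPM (0.86 ± 0.10), and HOS15 (AT5G67320), another partner, by 0.37 ± 0.08.

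Decreases in hda9-1 without ABA lay in several lists. NADPH oxidases fell at 5 of 8 genes (median -0.67, adjusted p = 1.9e-05, and adjusted p = 0.25 with an estimated correlation), 6 adjusted over the list alone, as AT4G25090 (RBOHG, -1.14 ± 0.16) and the root hair oxidase gene RHD2 (AT5G51060, -0.93 ± 0.18). Root markers fell at 3 of 18 (median -0.60, adjusted p = 5.7e-04, and adjusted p = 0.25 with an estimated correlation), 7 adjusted over the list alone, as the nitrate transporter gene NRT2:1 (AT1G08090, -2.52 ± 0.51). Auxin genes fell at 4 of 12 (median -0.54, adjusted p = 0.014, and adjusted p = 0.25 with an estimated correlation), with 1 higher and 4 lower adjusted over the list alone, as IAA29 (AT4G32280, -2.01 ± 0.18). ABA-induced markers fell at 7 of 22 and rose at 1 (median -0.37, adjusted p = 0.034, and adjusted p = 0.73 with an estimated correlation), with 9 lower adjusted over the list alone, as RAB18 (AT5G66400, -1.13 ± 0.19) and LTI65 (-1.48 ± 0.28). The marker list was not called without WT_noABA replicate 1 (adjusted p = 0.080) or hda9_noABA replicate 2 (0.066) or 3 (0.050). Jasmonate genes fell at 2 of 13, also adjusted over the list alone (adjusted p = 0.039, and adjusted p = 0.73 with an estimated correlation), which were OPR3 (AT2G06050), a synthesis gene, at -0.97 ± 0.13 and JAZ1 at -0.69 ± 0.16. That call was lost without WT_noABA replicates 1 (adjusted p = 0.067) or 3 (0.098), or hda9_noABA replicates 2 (0.066) or 3 (0.10). Whichever library was left out, 1 of the 3 root marker calls and 1 of the 4 auxin calls held, and after removal of length trends 2 auxin genes were lower and 1 higher, and 2 root markers were lower.

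Peroxiredoxins and thioredoxins, the thiol redox proteins, rose in hda9-1 without ABA at 8 of 30 genes and fell at 2 (median 0.15, adjusted p = 0.032, and adjusted p = 0.73 with an estimated correlation), with 10 and 2 adjusted over the list alone, 12 and 0 after removal of length trends, and 4 of the 10 calls holding whichever library was left out. The plastid genes NTRC, ATHM2 (AT4G03520, also TRXM2) and TRXF2 (AT5G16400) rose by 0.56 ± 0.09, 0.55 ± 0.10 and 0.49 ± 0.09. This list was not called without WT_noABA replicate 1 (adjusted p = 0.16), where its mean was -0.028 against 0.013 with all libraries, or hda9_noABA replicate 2 (adjusted p = 0.066). Flowering regulators rose at 2 of 11 (median 0.52, adjusted p = 0.033, and adjusted p = 0.25 with an estimated correlation), 4 adjusted over the list alone, as AGL20 by 0.63 ± 0.13, but the list was not called without hda9_noABA replicate 1 (adjusted p = 0.080) or after removal of the length trend (adjusted p = 0.055). Chloroplast-encoded genes were lower at 5 of 78 (median -0.63, adjusted p = 3.8e-06, and adjusted p = 0.73 with an estimated correlation), 1 adjusted over the list alone, and 0 of these calls held whichever library was left out. Mitochondrially encoded genes were lower at 3 of 25 (median -0.61, adjusted p = 0.0016, and adjusted p = 0.25 with an estimated correlation), 6 adjusted over the list alone, as ATMG01360, at 4.4 ± 0.711 CPM in wild type and 1.66 ± 0.489 CPM in hda9-1, and 1 of the 3 calls held whichever library was left out. After removal of length trends 4 flowering regulators were higher, 8 chloroplast-encoded and 5 mitochondrially encoded genes were lower, and uncalled lists had, as higher and lower members, 11 and 1 for photosynthesis (against 0 and 2), 5 and 0 for superoxide dismutases (against 2 and 0) and 8 and 3 for the ascorbate-glutathione list (against 5 and 4). In uncalled lists, AOX1A rose by 0.71 ± 0.14, the peroxisomal ascorbate peroxidase gene APX3 (AT4G35000) by 0.50 ± 0.08 and CAT1 (AT1G20630) by 0.58 ± 0.11, while DHAR1 (-0.68 ± 0.13), NAC6 (-0.77 ± 0.14), LHCB2.1 (AT2G05100, -0.51 ± 0.12) and CYP71A13 (AT2G30770, -3.42 ± 0.60), of camalexin synthesis, fell. Receptors were called without WT_noABA replicate 1 (adjusted p = 0.023), superoxide dismutases and catalases without WT_noABA replicate 3 (0.049) and photosynthesis without hda9_noABA replicate 3 (0.012).

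In this comparison edgeR called 2835 genes, 1461 higher and 1374 lower, and 7648 genes did not overlap (36.6%, against 10% by chance). With library size alone the split was 980 higher and 1810 lower, and after removal of length trends 2823 and 1103. At least 2-fold, 36 genes were higher and 327 lower. The number called was 1752, 1382 and 1576 without WT_noABA replicates 1, 2 and 3, and 1669 and 1540 without hda9_noABA replicates 2 and 3, and 984 calls (577 higher, 407 lower) held whichever library was left out. Of the 2-fold changes 12 and 134 held so. The numbers 2-fold higher were 20 and 23 without WT_noABA replicates 2 and 3, and those 2-fold lower 181 and 173 without WT_noABA replicate 2 and hda9_noABA replicate 3. The shortest genes had a median of -0.14 and the longest 0.05. The median, mean and test differed in sign for PP2C, SnRK2, alternative respiration, respiratory chain, ascorbate-glutathione, photosynthesis, histone deacetylase, seed and mitotic lists.

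With ABA, peroxiredoxin and thioredoxin genes were higher in hda9-1 than in wild type. Of 30 genes 15 were higher and 0 lower (median 0.43, adjusted p = 1.3e-07, and adjusted p = 0.44 with an estimated correlation), 19 adjusted over the list alone, and 7 calls held whichever library was left out. AT3G52960 (PRXIIE), a plastid peroxiredoxin, rose from 80.6 ± 6.99 to 135 ± 11.8 CPM (0.74 ± 0.12), ATHM2 by 0.63 ± 0.10 and 2-Cys Prx B (AT5G06290) by 0.50 ± 0.09. Superoxide dismutases and catalases were higher at 6 of 11 (median 0.38, adjusted p = 0.0072, and adjusted p = 0.37 with an estimated correlation), with 6 higher and 1 lower adjusted over the list alone, but each of these 6 calls was lost without some library. CSD2 (AT2G28190), a plastid copper/zinc enzyme, had 68.4 ± 15.6 CPM in wild type and 248 ± 125 CPM in hda9-1 (1.86 ± 0.42). It lost its call without WT_ABA replicate 1 (adjusted p = 0.089) or 2 (0.086) or hda9_ABA replicate 1 (0.058). CSD2 had fallen after ABA in wild type (-1.65 ± 0.42) and was not called in hda9-1 (0.13 ± 0.41). FSD3 (0.74 ± 0.18) lost its call without WT_ABA replicate 3 or hda9_ABA replicate 3 (both adjusted p = 0.064). Glutathione S-transferases were higher at 3 of 10 (median 0.40, adjusted p = 0.034, and adjusted p = 0.63 with an estimated correlation), 4 adjusted over the list alone, as GSTU1 (AT2G29490) by 0.80 ± 0.15 and GSTU19 (AT1G78380) by 0.53 ± 0.11. That list was not called without WT_ABA replicate 1 (adjusted p = 0.12), hda9_ABA replicate 1 (0.10) or 3 (0.089), or after removal of the length trend (0.060). The shortest genes had a median of 0.20 and the longest -0.04, and median exon lengths were 1110.5, 1265 and 1181.5 nt in these 3 lists.

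**Figure D3:**
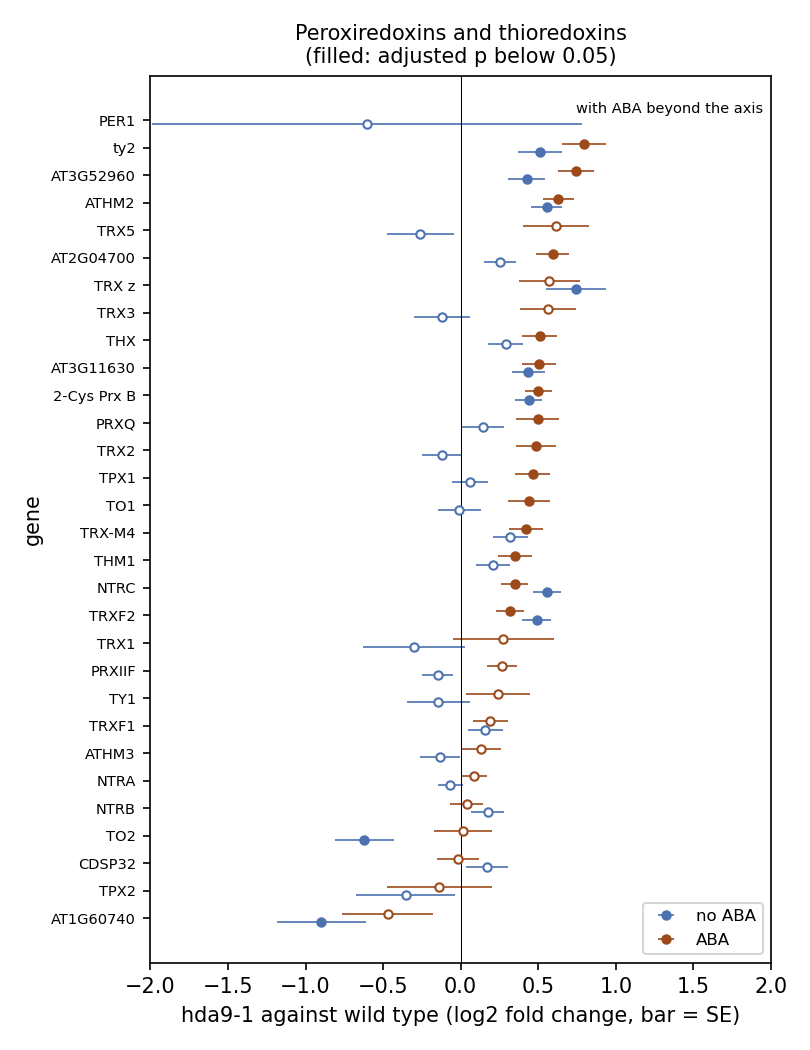
Log2 fold change of hda9-1 against wild type (horizontal axis, bars are SE) for each of 30 peroxiredoxin and thioredoxin genes without and with ABA, filled where the adjusted p is below 0.05. Without ABA 8 genes were called higher and 2 lower, with ABA 15 higher and 0 lower, and PER1 with ABA lies beyond the axis.

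Other lists were lower in hda9-1 with ABA. NADPH oxidases were lower at 4 of 8 (median -0.53, adjusted p = 0.0012, and adjusted p = 0.49 with an estimated correlation), 6 adjusted over the list alone, as RBOHD (-0.53 ± 0.11), and 2 of the 4 calls held whichever library was left out. Guard cell markers were lower at 3 of 8 (median -0.51, adjusted p = 8.2e-04, and adjusted p = 0.37 with an estimated correlation), 5 adjusted over the list alone, as the stomatal regulator FMA (AT3G24140, -0.79 ± 0.11) and the potassium channel gene KAT1 (AT5G46240, -0.71 ± 0.12). Root markers were lower at 1 of 18, also adjusted over the list alone (median -0.54, adjusted p = 9.7e-04, and adjusted p = 0.37 with an estimated correlation), which was CASP2 (AT3G11550) at -1.05 ± 0.19. Jasmonate genes were lower at 1 of 13, also adjusted over the list alone (adjusted p = 0.037, and adjusted p = 0.63 with an estimated correlation), which was OPR3 at -0.95 ± 0.13, and the list was not called without WT_ABA replicate 2 (adjusted p = 0.16) or hda9_ABA replicate 1 (0.14) or 2 (0.060), or with a filter of 1 CPM (0.051). Among the largest decreases were the histone H2A gene HTA4 (AT4G13570), from 5.94 ± 0.747 to 0.908 ± 0.409 CPM (-2.70 ± 0.36), AT4G13575 (-2.01 ± 0.26), the cell wall gene XTH15 (AT4G14130), from 211 ± 18.0 to 60.9 ± 13.9 CPM (-1.79 ± 0.19), AT2G05160 (-1.76 ± 0.22) and AT5G26270 (-1.76 ± 0.32). AT5G56370 rose by 1.81 ± 0.24. Other genes of the same rule lost their calls without single libraries. These were MRN1 (AT5G42600, 3.44 ± 0.71) without WT_ABA replicates 1 (adjusted p = 0.052) or 2 (0.050), and UGT73C1 (AT2G36750, 2.26 ± 0.58) without WT_ABA replicates 1 (0.099), 2 (0.096) or 3 (0.053) or hda9_ABA replicate 3 (0.076). AT4G01985 (1.82 ± 0.42) lost its call without WT_ABA replicates 1 (0.050) or 3 (0.057) or hda9_ABA replicate 3 (0.062). SEP3 (AT1G24260, 1.59 ± 0.45) did so without WT_noABA replicate 2 (0.051), WT_ABA replicates 1, 2 or 3 (0.12, 0.089 and 0.064) or hda9_ABA replicates 1 (0.058) or 3 (0.11), and AIR1 (AT4G12550, -2.16 ± 0.58) without WT_ABA replicates 1, 2 or 3 (0.072, 0.083 and 0.075) or hda9_ABA replicates 1, 2 or 3 (0.11, 0.060 and 0.098).

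Among lists not called with ABA, the respiratory chain had 6 higher and 0 lower of 25 (adjusted p = 0.059; 7 adjusted over the list alone), and each of the 6 calls was lost without some library. The ascorbate-glutathione list had 6 higher and 1 lower of 25, with GR (AT3G54660), a glutathione reductase gene, up by 0.38 ± 0.09 and DHAR3 (AT5G16710) by 0.36 ± 0.08. NDA2 (AT2G29990) rose by 0.83 ± 0.14 and NDB1 (AT4G28220) fell by 0.49 ± 0.10. PWR rose by 0.59 ± 0.10, AAO3 (AT2G27150), of ABA synthesis, by 0.37 ± 0.08 and the clock-controlled GRP7 (AT2G21660) by 0.78 ± 0.16, while CCA1 (-0.85 ± 0.17), LHCB2.1 (-0.61 ± 0.12) and IAA29 (-1.43 ± 0.17) fell. ABA-induced markers had 2 higher and 2 lower of 22, and PP2C phosphatases 0 of 9 called. The respiratory chain was called without WT_ABA replicate 3 (adjusted p = 0.025), mitochondrial stress markers without hda9_noABA replicate 1 (0.032), flowering regulators without hda9_ABA replicate 3 (0.049), mitochondrially encoded genes after removal of the length trend (0.044), and chloroplast-encoded genes without WT_ABA replicate 1 (2.0e-06), hda9_noABA replicate 1 (0.042) or hda9_ABA replicate 2 (0.017). The median, mean and test differed in sign for the SnRK2, photosynthesis and senescence lists.

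With ABA edgeR called 2660 genes, 1570 higher and 1090 lower, and 6174 genes did not overlap (29.5%, against 10% by chance). A fit on the 2 groups compared called 1433 genes. With library size alone the split was 1164 higher and 1372 lower, and after removal of length trends 2513 and 1057. At least 2-fold, 88 were higher and 160 lower. Without WT_ABA replicates 1, 2 and 3 the number called was 1075, 1328 and 1527, and without hda9_ABA replicates 1, 2 and 3 it was 1348, 4640 and 1560. Of the calls 853 (513 higher, 340 lower) held whichever library was left out, 30 and 79 of them 2-fold. The number 2-fold higher was 44, 48, 52, 255 and 44 without WT_ABA replicates 1 and 2 and hda9_ABA replicates 1, 2 and 3. The number 2-fold lower was 100, 102 and 293 without WT_ABA replicates 1 and 3 and hda9_ABA replicate 2. With and without ABA 1095 genes differed between genotypes in the same direction, 644 higher and 451 lower, where independent calls would give 110 and 71.6, and fold changes correlated across genes at r = 0.41 and rho = 0.46. Calls in a single condition numbered 1739 without and 1564 with ABA, of which 86.9% and 80.8% had the same sign in the other. That overlap was 666 and 665 without WT_noABA replicates 1 and 2, 602, 631 and 675 without WT_ABA replicates 1, 2 and 3, and 667 without hda9_noABA replicate 2. CDT1 (AT1G52827), named after its values were seen, was called in opposite directions, -1.02 ± 0.27 without and 1.04 ± 0.24 with ABA, with an adjusted p of 0.137 for the difference.

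Whether the response to ABA differed between the genotypes was tested as the difference of both responses. No single gene was called for it by edgeR (0 of 20924, lowest adjusted p = 0.056), with 2467 genes at an unadjusted p below 0.05 where 1046.2 would arise by chance. limma-voom called 0 genes, and DESeq2 called 129, 112 higher and 17 lower. The number was 1612 without hda9_ABA replicate 2, 3 without WT_noABA replicate 1, 2 without WT_noABA replicate 2 or hda9_noABA replicate 1, and 1 without WT_ABA replicate 3, hda9_noABA replicate 3 or hda9_ABA replicate 3. In the genes with the smallest p in their lists, the difference was 0.61 ± 0.18 for TRX2 (AT5G39950, also TRXH2), 1.33 ± 0.38 for ATCG00210 and 0.90 ± 0.21 for CSD1 (AT1G08830), with adjusted p of 0.26, 0.25 and 0.21. Camera called 6 lists. The respiratory chain (mean 0.16, adjusted p = 0.041, and adjusted p = 0.88 with an estimated correlation), peroxiredoxins and thioredoxins (0.36, 0.0029, and adjusted p = 0.88 with an estimated correlation), glutathione S-transferases (0.70, 0.0015, and adjusted p = 0.83 with an estimated correlation), ABA-induced markers (0.47, 0.0029, and adjusted p = 0.83 with an estimated correlation) and chloroplast-encoded genes (0.86, 1.5e-13, and adjusted p = 0.83 with an estimated correlation) were more positive in hda9-1. Guard cell markers were more negative (-0.29, 0.016, and adjusted p = 0.83 with an estimated correlation). The mean of ABA-induced markers in hda9-1 against wild type was -0.49 without ABA and -0.025 with ABA. Their difference thus came from a lower untreated level in hda9-1, not from a higher treated level. For chloroplast-encoded genes these means were -0.58 and 0.28.

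Adjusted over the list alone, 6 ABA-induced markers were more positive, 1 guard cell marker was more negative, and 0 genes of the other 4 lists were called for the difference. The respiratory chain was not called without WT_noABA replicates 2 (adjusted p = 0.11) or 3 (0.18), WT_ABA replicates 1 (0.055) or 2 (0.15), hda9_noABA replicates 1 (0.22) or 3 (0.090) or hda9_ABA replicates 2 (0.18) or 3 (0.099), without organelle genes (0.074) or after removal of the length trend (0.41). Guard cell markers were not called without WT_noABA replicate 1 (0.058), WT_ABA replicate 2 (0.054), hda9_noABA replicate 1 (0.10) or hda9_ABA replicate 2 (0.20), and peroxiredoxins and thioredoxins not after removal of the length trend (0.70). By fry 0 of the 6 lists were called (adjusted p 0.37 to 0.46). Other lists were called only under some settings. Removal of length trends added photosynthesis (mean -0.16 against 0.026 before, adjusted p = 5.8e-06), mitochondrially encoded genes (0.0081), salicylic acid genes (0.038) and NADPH oxidases (0.047). Photosynthesis was also called without hda9_noABA replicate 3 (mean -0.10, adjusted p = 0.0034), ascorbate-glutathione genes without hda9_noABA replicate 2 (0.044) and auxin genes without WT_noABA replicate 2 (0.029). Mitochondrially encoded genes were also called without WT_ABA replicate 1 (0.021), hda9_noABA replicate 1 (0.047) or hda9_ABA replicate 1 (0.042), or with a filter of 1 CPM (0.039). For the difference the shortest genes had a median of 0.32 and the longest -0.11. Relative to the mean of all libraries, the shortest genes deviated by 0.29 and 0.34 in hda9_ABA replicates 1 and 3, by -0.09 in replicate 2, by -0.14 to -0.09 in hda9-1 without ABA, and by -0.06 to 0.07 in wild type. Across the 4 comparisons of 2 groups and the difference, 43 lists were called. Of these, 8 held with an estimated correlation, which were ABA-induced markers, PP2C phosphatases, SnRK2 kinases with ABA transcription factors, ABA metabolism and senescence after ABA in wild type, and ABA-induced markers, PP2C phosphatases and ABA metabolism after ABA in hda9-1.

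**Figure D4:**
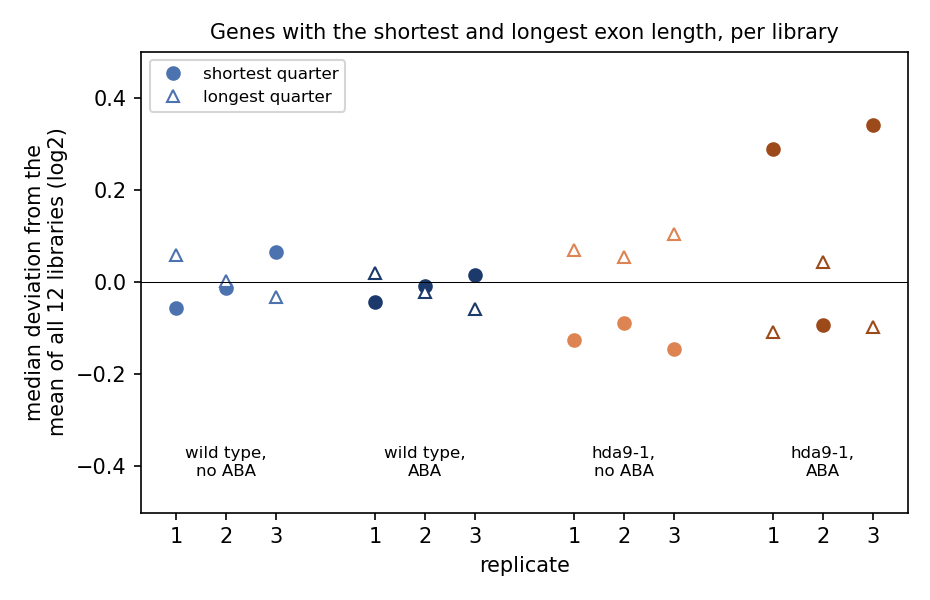
Median deviation of log2 CPM from the mean of all 12 libraries (vertical axis) for the genes with the shortest (up to 1273 nt) and the longest (at least 2368 nt) exon length, for each replicate of each group (horizontal axis). The shortest genes lie at 0.29 and 0.34 in hda9-1 with ABA replicates 1 and 3 and at -0.09 in replicate 2.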

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

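The tests of evenly spread background reads, of the root tissue share, of HDA9 in a single library and of the strength of the ABA response in that library were chosen after the results were seen, and so was the removal of exon length and GC trends. Results are listed here because a test of the difference between the genotypes' ABA responses passed, or because all samples of both genotypes moved in opposite directions.

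In 6 gene lists the response to ABA differed between hda9-1 and wild type by camera with the preset correlation. The mean difference (hda9-1 minus wild type, log2) was 0.47 for ABA-induced markers (adjusted p = 0.0029), 0.16 for the respiratory chain (0.041), 0.36 for peroxiredoxins and thioredoxins (0.0029), 0.70 for glutathione S-transferases (0.0015), -0.29 for guard cell markers (0.016) and 0.86 for chloroplast-encoded genes (1.5e-13). With an estimated correlation the adjusted p was 0.83 to 0.88 for these lists. A difference can come from either treatment. The means in hda9-1 against wild type, without and with ABA, were -0.49 and -0.025 for ABA-induced markers and -0.58 and 0.28 for chloroplast-encoded genes. They were -0.32 and 0.38 for glutathione S-transferases, 0.013 and 0.37 for peroxiredoxins and thioredoxins, -0.034 and 0.13 for the respiratory chain, and -0.23 and -0.52 for guard cell markers. The respiratory chain was not called without WT_noABA replicates 2 (adjusted p = 0.11) or 3 (0.18), WT_ABA replicates 1 (0.055) or 2 (0.15), hda9_noABA replicates 1 (0.22) or 3 (0.090), or hda9_ABA replicates 2 (0.18) or 3 (0.099). Guard cell markers were not called without WT_noABA replicate 1 (0.058), WT_ABA replicate 2 (0.054), hda9_noABA replicate 1 (0.10) or hda9_ABA replicate 2 (0.20). After removal of length trends the respiratory chain (0.41) and peroxiredoxins and thioredoxins (0.70) were not called.

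Among named and oppositely called genes, 5 moved in opposite directions in all samples. AT1G76770, AT3G61560 and APT4 were looked at because they were called in opposite directions, so this adds nothing for them. How many of all tested genes would move so by chance was not computed. The difference was 0.79 for TCH2 (adjusted p = 0.242), 3.05 for ATMG00516 (0.232), 6.10 for AT1G76770 (0.229), 0.94 for AT3G61560 (0.217) and 4.79 for APT4 (0.229), so edgeR's test of the difference was not passed at any of them.

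Without ABA, more genes were at least 2-fold lower (327) than 2-fold higher (36) in hda9-1. Background reads spread evenly over genes in wild type are argued against, because they would lift every gene, and 22.0% of all 23655 nuclear genes lay below 0.5 times the median loss of 1.39 CPM per kb of exon in wild type without ABA (95% interval 21.5 to 22.5%). Exon length and GC trends are argued against as the whole cause. After their removal 254 genes were 2-fold lower and 80 higher, a ratio of 3.18 (2.46 to 4.14) against 9.08 before. There were more higher genes and fewer lower ones than before. Both intervals treat genes as independent and leave out the spread between libraries. A smaller share of root tissue in hda9-1 seedlings stays open, since the root markers' median was -0.60 with a range of 1 median absolute deviation from -1.07 to -0.13, against -1.38 in the 2-fold lower genes. The genotype itself stays open as the biological explanation, beside a trend with expression level that was not tested as a cause, with median log2 fold changes from -0.43 in the lowest decile of expression to 0.12 in the highest (-0.25 and 0.14 after removal of length trends) and 21510 to 21838 genes detected in hda9-1 libraries against 21872 to 22189 in wild type.

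The number of genes whose ABA response differed rested on hda9-1 with ABA replicate 2, with 0 called with it and 1612 without it. A wild-type sample or a mix with one is argued against by its HDA9 level of 4.78 CPM, far from 16.3 to 16.8 CPM in wild type with ABA. A weaker ABA response of that library is argued against by its position of 1.01 between untreated (0) and treated (1) wild type over 2048 genes, inside the range of 0.976 to 1.04 of the other treated libraries. Exon length and GC trends stay open, since 171 genes were called without that library after their removal, and only 152 of the 1612 were among these. Genes called higher without it had a median exon length of 925 nt and those lower 2717 nt, and a difference of genotypes in the ABA response cannot be told apart from a length trend shared by the other 2 libraries.

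Peroxiredoxin and thioredoxin genes were higher in hda9-1 with ABA at 15 of 30 genes. Exon length and GC trends are argued against as the whole cause, because the list's median was 0.34 after their removal against 0.43 before. Over all genes the median was then 0.052 against 0.015. After removal 15 listed genes were called higher, 14 of them the same genes. That count alone says little, since removal raised higher calls over all genes from 1570 to 2513. Without ABA 12 listed genes were higher and 0 lower after removal. The expression level of the listed genes is argued against, because the list's median was at percentile 100 of 10000 lists matched on expression, of which 95% lay between -0.08 and 0.16. Those lists were drawn gene by gene and were not matched on exon length. Their range therefore leaves out genes that move together, and the percentile does not measure how unusual such a list is. A candidate explanation is the genotype, as a hypothesis found and tested on the same samples. This explanation stays limited by the test with an estimated correlation (adjusted p = 0.44) and by the 7 of 15 calls that held whichever library was left out. A changed share of tissues was not tested for this list. Root markers (median -0.54) and guard cell markers (median -0.51) were lower in the same comparison, and floral markers were not called.

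Other splits of the samples were counted for each comparison. With 3 against 3 samples there are 10 splits, which cannot give a share under 0.05. In each comparison 1 split, the real one, had the most called genes. Every other split mixes the 2 groups, which moves a real difference into the spread within groups. Low numbers of genes in those splits were thus set by the design, and no conclusion is drawn from them. Mixed splits also keep part of a real difference, so their numbers of gene lists are not of chance alone. The real split and the highest of the others called 6474 and 0 genes for ABA in wild type, 8767 and 0 for ABA in hda9-1, 2835 and 3 for genotype without ABA, and 2660 and 0 for genotype with ABA. For gene lists the real and highest other numbers were 11 and 13, 10 and 8, 9 and 12, and 7 and 8, and 5, 1, 4 and 3 splits, the real one included, gave as many as the real one. For the difference of responses, 9 of 100 splits of genotype within treatment, the real one included, gave as many genes with an unadjusted p below 0.05 as the real 2467 (highest other 4484), and 50 of 100, the real one included, gave as many lists as the real 6 (highest other 13), so chance is not excluded for either. A split that exchanges genotypes in 1 treatment alone carries genotype effects into the difference, so these numbers are not of chance alone.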

How the results depend on the processing

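The removal of exon length and GC trends, with or without hda9_ABA replicate 2, was chosen after seeing the data, and the other alternatives were planned. No named gene changed its sign in a call and no called list changed the direction of its test, but some list means and majorities turned. The mean of peroxiredoxins and thioredoxins between genotypes without ABA was -0.028 without WT_noABA replicate 1 against 0.013, and that of photosynthesis for the difference of responses was -0.16 after removal of length trends and -0.10 without hda9_noABA replicate 3 against 0.026. Higher calls outnumbered lower calls in the 4 comparisons of 2 groups, and lower calls outnumbered higher ones with upper-quartile factors for ABA in wild type (3964 and 3024), ABA in hda9-1 (4855 and 4298), genotype without ABA (1613 and 1195) and with ABA (1316 and 1297). They did so with library size alone for ABA in wild type (3603 and 3073) and for genotype without (1810 and 980) and with ABA (1372 and 1164), after removal of length trends for ABA in wild type (3742 and 3652) and in hda9-1 (4807 and 4125), with a filter of 1 CPM for genotype without ABA (1436 and 1420), and without hda9_noABA replicate 1 for both genotype comparisons. Of the numbers that answer the comparisons, with the 2 HDA9 fold changes, 194 alternative values were unchanged and 38 were not. Unchanged meant within 1.5 times of the main value for numbers of genes or lists. For HDA9 it meant the same direction and side of the threshold. For named genes 8432 values kept direction and side of the threshold, 606 lost the call and 26 gained it, and for gene lists these numbers were 2548, 90 and 47. With fry in place of camera, 15 list calls were lost and 18 gained. HDA9 stayed called in every alternative. An adjusted p below 0.01 gave 4132 genes for ABA in wild type, 986 for genotype without ABA and 867 with ABA, 3431 for the shared ABA response and 359 for the shared genotype effect, as the stricter threshold must lower them. A fit on the 2 groups compared gave 1433 genes for genotype with ABA, but 3568 without ABA, 8369 for ABA in wild type and 6929 in hda9-1. The main fit shares 1 estimate of the spread per gene over all groups. The median SD within a group was 0.170 log2 in hda9-1 with ABA and 0.104 to 0.122 in the other groups. Both comparisons that use hda9-1 with ABA gave fewer genes than in the main fit, and both others gave more. The cause was not tested. For the difference of ABA responses, upper-quartile factors, library size alone, no low-count filter and removal of length trends each gave 1 gene, DESeq2 gave 129 and removal of length trends without hda9_ABA replicate 2 gave 171, and the cause was not tested. Removal of length trends gave 1895 genes for the shared genotype effect, and camera with an estimated correlation gave 8 list calls in place of 43, and the causes were not tested. Leaving out 1 library at a time gave 4707 to 7437 genes for ABA in wild type, 7300 to 9572 for ABA in hda9-1, 1382 to 3808 for genotype without ABA, 1075 to 4640 with ABA and 0 to 1612 for the difference. It gave 4068 to 5272 genes for the shared ABA response, 602 to 1330 for the shared genotype effect and 39 to 45 list calls. With the replicate number as a replicate block the 5 comparisons gave 6237, 8458, 2539, 2344 and 0 genes. Scaling moved the median of all genes by under 0.1, but turned the sign of small list medians, among them PP2C phosphatases between genotypes, mitotic genes between genotypes without ABA and the respiratory chain after ABA in hda9-1. Depth limits the organelle genes and genes near 0 counts, whose folds are bounds or ratios with wide intervals.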

Other observations

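The iron and copper tests and the tests of a deletion and of chance neighbours here were chosen after the values were seen, and the iron and copper gene lists were written then.

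Iron uptake genes were lower after ABA. IRT1, the main iron transporter of roots, had log2 fold changes of -2.49 ± 0.40 in wild type and -3.34 ± 0.42 in hda9-1 (SE, n = 3), and the ferric reductase gene FRO2 -2.61 ± 0.41 and -3.33 ± 0.43. Of 20 iron deficiency genes, 11 were called lower and 1 higher in wild type, with a median of -0.77. The fall did not cover the whole set. PYE rose by 0.84 ± 0.15, and FRO3, bHLH38, bHLH39, BHLH100, BHLH101, NAS4, BTS and OPT3 were not called. A fall of the set on average stays open, since camera with an estimated correlation gave p = 0.234, against p = 5.7e-04 with the preset one. Neither p is an independent test, since the list holds AT3G12900 and CYP82C4, large decreases already seen. In hda9-1 against wild type 4 of the 20 genes were lower without ABA (median -0.64) and 5 with ABA (median -0.93). Camera with an estimated correlation gave p = 0.074 and p = 0.078 there. IRT1 is also among the root markers, whose medians were -0.60 without and -0.54 with ABA in the same comparisons, so a smaller share of root tissue stays open here too.

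Copper/zinc superoxide dismutase genes may follow copper supply, which differs in its effect on CSD2 and on the iron enzyme gene FSD1. Across 12 libraries, deviations from group means of CSD2 and FSD1 ran against each other (rho = -0.76, permutation p = 0.034, r = -0.74, permutation p = 0.022, and r = -0.81 without the 2 libraries farthest in CSD2). This was the only relation between levels of 2 genes computed across libraries. CSD2 varied within groups, from 141 to 283 CPM in wild type without ABA and from 167 to 391 CPM in hda9-1 with ABA. The relation is across all groups and does not show that copper differed between genotypes. CSD2 fell after ABA in wild type (-1.65 ± 0.42, adjusted p = 0.016 by edgeR) and was not called in hda9-1 (0.13 ± 0.41). Between genotypes without ABA it was not called either (0.07 ± 0.41). CSD1 (-0.61 ± 0.15) and CCS (-1.33 ± 0.31) were also called lower in wild type and not called in hda9-1 (0.29 ± 0.15 and -0.75 ± 0.31). The difference of responses was not called at any of them. In hda9-1 against wild type with ABA, where CSD2 was higher (1.86 ± 0.42), copper supply would need FSD1 to be lower. FSD1 was not lower (0.49 ± 0.55, adjusted p = 0.61 by edgeR), so this prediction was not met. Because the SE of FSD1 is large, copper supply stays open for that difference.

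HTA4 and its neighbours on chromosome 4, AT4G13572 (7887440 to 7888748, TAIR10.1) and AT4G13575 (7890249 to 7893761), were lower in hda9-1. The log2 fold changes of HTA4 were -2.62 ± 0.37 without and -2.70 ± 0.36 with ABA, and those of AT4G13572 -2.33 ± 0.34 and -1.75 ± 0.33. Reads shared between these genes are argued against, since their transcripts share 0% of 31-mers. Chance neighbours stay open, since the test counts runs of 3, a length taken from this run. The 50 genes 2-fold lower in both comparisons, placed at random, gave as many such runs in a share of 4e-04 of 10000 draws. All 6 hda9-1 libraries held reads of the 3 genes, with 16 to 54 counts for HTA4, 25 to 65 for AT4G13572 and 107 to 225 for AT4G13575. Reads that similar genes elsewhere may share with them were not tested, so a deletion in every hda9-1 plant stays open. Another change of this region was not tested.

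Genes that changed in both genotypes after ABA changed slightly more in hda9-1. The median absolute log2 fold change over 5176 genes was 0.72 in wild type and 0.82 in hda9-1, and 63.8% had the larger change in hda9-1, without a test of this difference. It was not computed again after removal of length trends. After ABA the shortest and longest genes had medians of 0.28 and -0.15 in hda9-1, against -0.04 and -0.03 in wild type. A stronger response in hda9-1 therefore cannot be told apart from this length trend.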
